A study of Drosophila melanogaster with 3 samples.

How the data were processed

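Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been performed on whole embryos of the fruit fly Drosophila melanogaster, aged 0 to 24 h and of both sexes. The line carried a transgene in which green fluorescent protein (GFP) is fused to the C-terminus of CG9797, the gene also named M1BP (Motif 1 binding protein). Its product is a zinc-finger protein known to bind Motif 1, a sequence element of core promoters. Per the labels, chromatin was sheared by sonication to 200 to 800 bp and 3 biological replicates were made, which form the 1 group of the series. The replicate numbers are those of the labels. The labels disagree on what the libraries are: a free-text line calls them input controls, whereas the assay title, the antibody field and a separately listed control experiment describe them as immunoprecipitated libraries. They were analysed as immunoprecipitated libraries. The antibody field names CG9797 and does not say whether an antibody against GFP was used.

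The authors deposited 5 peak lists on assembly dm6. Per the deposited notes, each replicate's relaxed list was called from that replicate's alignment and 1 control file shared by all replicates, and a pooled relaxed list was called from the 3 alignments together with the same control. A thresholded list, filtered by irreproducible discovery rate (IDR), was derived from these 4 lists. Each relaxed list holds 30000 entries, so it contains background as well as peaks, and the thresholded list holds 4598. The aligner, the peak caller, the IDR threshold and all versions are not given in the sources used here. The deposited signal value of each peak is a score set by the authors' peak caller, whose scale is not given. The deposited −log10 q-value of each peak was calculated by the authors' peak caller and stops at a ceiling, which 4445 of the 4598 thresholded peaks reach (96.7%). The deposited summit position is an offset in bp from the start of each interval. Scores were used to rank, filter and describe peaks within 1 list, and between replicates they were compared by rank correlation alone. The files hold no read counts, so the sequencing depth of each replicate is unknown. Control libraries were not analysed here. All 4598 thresholded peaks are the 4598 strongest entries of the pooled list.

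Coordinates were combined with the Ensembl release 115 annotation (BDGP6.54) and the NCBI Release 6 genome sequence, which share dm6 coordinates. The largest peak end lay inside each of the 6 main chromosome arms (2L, 2R, 3L, 3R, 4 and X), and 99.9% of 16213 annotated start codons read ATG in the sequence. The 13945 protein-coding genes on these arms were analysed, with 19252 distinct start sites, and 290 tRNA genes. Coordinates are given counted from 1. A peak was called a promoter peak when its summit lay within 250 bp of a start site of a protein-coding gene, and a gene was called bound when a thresholded summit lay within 250 bp of any of its start sites. One peak can mark more than 1 gene. To measure the spread between replicates, each measure was also taken on the 4598 strongest peaks of each replicate, and means and standard deviations (SD) are over these 3 lists.

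The share of promoter peaks was compared with 1000 circular shifts of the summits within each arm. Gene lists (22, from ribosomal proteins to odorant receptors, fixed before the data were examined) were tested with two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists; 5 list symbols matched no gene name. For 10 core promoter and insulator motifs, a match within 100 bp of the summit was compared with windows 1000 bp to the left of the same summits by an exact binomial sign test, and a match within 100 bp of the most upstream start site was compared between bound and unbound genes by Fisher's exact test. Both families were adjusted by Benjamini-Hochberg. Medians of the signal value were compared by two-sided permutation tests with 100000 resamples, whose smallest possible p is 1e-05; that of the circular shifts is 0.001. Odds ratios are conditional estimates with 95% intervals, and 95% intervals of shares are Wilson intervals, which cover counting error only. Peaks and genes are not biological replicates, so these p-values describe the lists, and the values per replicate show the spread between libraries. A pair of replicates was compared by the share of the 4598 strongest peaks of one with a summit within 100 bp of those of the other. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

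The genes named in the text were fixed by a rule before the data were examined. It takes M1BP itself, the genes at the 10 strongest thresholded peaks, the 3 strongest bound members of every list that passed the threshold of 0.05, the first 2 unbound members in alphabetical order of such lists, and all 8 homeotic genes. It also takes the nearest gene of the 5 strongest peaks over 1000 bp from any start site, the 5 strongest promoter peaks without a Motif 1 match at up to 1 mismatch, and every bound member of lists with 5 or fewer.

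The tests were tested on simulated data. In 20 simulations of bound genes among the 13945, 49 of 52 lists of 30 genes or more were called when their bound share was raised from 30% to 60%, and 18 of 48 smaller lists. Of lists lowered to 5%, 49 of 59 with 30 genes or more and 25 of 41 smaller ones were called. Of 240 lists left at 30%, 12 were called, all among the lists of 30 genes or more. In 20 simulations of 4000 peaks, 10% were placed on Motif 1 sites of the genome and the rest at random positions. Motif 1 was found at 10.1% and called in 20 of 20, and other motifs were called in 18 of 180 tests. Other motifs may lie near real Motif 1 sites, so these 18 calls are not a rate of false calls. The random positions were not set at promoters, so the control windows were not checked for peaks that lie mainly there. The permutation test called 4 of 100 comparisons without a difference and 100 of 100 with one.

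Alternatives covered the distance to the start site (100, 500 and 1000 bp), a stricter signal threshold, peaks found in all 3 replicates, each replicate alone, and leaving out each replicate. They also covered the overlap that counts as shared, the choice of start site, the motif window, the control windows and 1 mismatch. A reduction of adjacent peaks to the strongest and a restriction to genes without a neighbouring opposite start site were chosen after seeing the data. No comparison between groups was possible, since the series holds 1 group.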

Results

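The series maps where the GFP-tagged factor M1BP (CG9797) sits on the genome of whole Drosophila embryos aged 0 to 24 h, in 3 biological replicates of 1 group. The thresholded list held 4598 peaks, of which 820 lay on arm 2L, 940 on 2R, 944 on 3L, 1103 on 3R, 7 on chromosome 4 and 784 on X (dm6). Their signal values ran from 261 to 5321 with a median of 538. In the relaxed lists, 8577 of 30000 entries in replicate 1, 3063 in replicate 2 and 3520 in replicate 3 had a −log10 q-value of at least 2. Read depth is unknown for all 3. In 722 places (15.7% of peaks) a thresholded summit had another within 250 bp to its left, at a median distance of 203 bp and never under 199 bp, and the left peak was the stronger in 716 of them. Counting such neighbours once left 3876 regions. The label conflict on whether the libraries are input or immunoprecipitated material applies to every value below.

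The strongest peak of the thresholded list, with a signal value of 5321, lay at ATPsynC, which encodes subunit c of the mitochondrial ATP synthase (3R, 31219415 to 31220099, summit 42 bp from a start site, outside the annotated gene). It ranked 2, 1 and 1 in replicates 1, 2 and 3. Next came the divergent promoter of alt and CG7655 (signal value 4457; 3R, 17682276 to 17682865), which ranked 4, 2 and 8, and Lk6, a protein kinase gene (4289; 3R, 11764326 to 11764820), which ranked 5, 3 and 7. The other 7 of the 10 strongest peaks lay between Jupiter, which encodes a microtubule-binding protein, and CG14710, between the autophagy gene Atg8a and BTBD9, at Map205, at RpL30, between CG16903 and Unc-76, between CG6693 and RpL3, and between the tubulin acetyltransferase gene Atat and the adaptor gene Shc. Their signal values ran from 3589 to 4118. Map205, a microtubule-associated protein gene, ranked 1 and 2 in replicates 1 and 3 but had no peak within 100 bp of that summit in replicate 2, where the best peak within 250 bp of its start site ranked 198.

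At M1BP itself, the strongest thresholded peak lay at 3R 8731881, 183 bp upstream of the annotated start site at 8731698, with a signal value of 577 and rank 2123. The best peak within 250 bp of its start site ranked 1992 in replicate 1 and 3101 in replicate 2, and replicate 3 listed none there.

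The replicates differed in how far their strongest peaks coincided. Of the 4598 strongest peaks, replicates 1 and 3 shared 74.4%, replicates 1 and 2 shared 51.1% and replicates 2 and 3 shared 44.3% (mean 56.6% ± 15.8, SD, n = 3 pairs). Across the thresholded peaks found in both lists of a pair, which are not independent replicates, Spearman's rho of the signal values was 0.870 for replicates 1 and 3 over 3896 peaks, 0.717 for replicates 1 and 2 over 3195, and 0.677 for replicates 2 and 3 over 2844. The 30000 entries of replicate 1 had a summit within 100 bp of 96.8% of the thresholded peaks, those of replicate 2 of 71.5% and those of replicate 3 of 86.6%. Among the strongest peaks, 1989 thresholded peaks (43.3%) were found in all 3 replicates, 1732 in 2, 762 in 1 and the rest in none. Replicate 2 less often had a summit within 100 bp of thresholded peaks of low GC content. Its share was 42.4% in the quartile of lowest GC (median 34.6%) and 91.5% in the highest (median 45.8%). The shares were 95.9% and 97.1% in replicate 1 and 90.8% and 81.3% in replicate 3. Shares by GC content were not taken at a wider distance, so absent peaks and displaced summits cannot be told apart here. The mean overlap rose to 73.2% with summits up to 250 bp apart and to 77.8% with 1 bp of interval overlap.

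**Figure D1:**
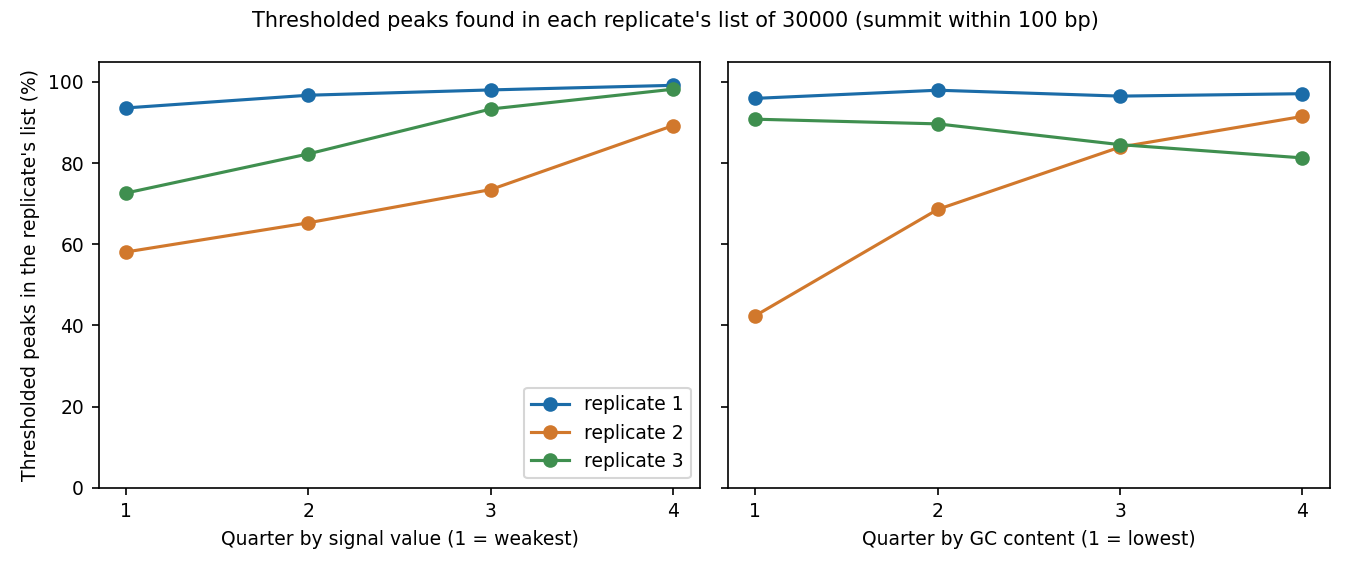
Share of the 4598 thresholded peaks (%) with a summit within 100 bp in each replicate's list of 30000 entries, by quartile of signal value (left) and of GC content in the 500 bp around the summit (right); each line is 1 replicate. Replicate 2 rises from 42.4% to 91.5% with GC content, while replicate 1 stays between 95.9% and 97.9%.

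M1BP peaks lay mainly at promoters. Of the thresholded peaks, 84.6% (3890 of 4598; 95% interval 83.5% to 85.6%) had the summit within 250 bp of a start site of a protein-coding gene, at a median distance of 48 bp. Circularly shifted summits gave a mean of 6.31% and at most 7.68%, so the share was 13.4-fold higher (permutation p = 0.001, the smallest possible). Replicates 1, 2 and 3 gave 82.2%, 81.0% and 81.4%, and each passed the same test. A further 315 peaks lay up to 1000 bp away, and 393 (8.55%) lay beyond, of which 239 were in introns and 140 between genes. The strongest of these distant peaks, with a signal value of 2077, lay in an intron of ush, a zinc-finger gene, 1366 bp from the nearest start site, that of cbt (2L, 480898 to 481286). The next 4 lay on 2L, in an intron of CG11050 (2033; 6612513 to 6612910) and between genes, nearest to CG31680 (1884; 20638473 to 20638878), CG10651 (1882; 20148316 to 20148709) and CG18810 (1443; 20647300 to 20647634). Distant peaks were weaker than promoter peaks, with a median signal value of 339 against 597 (permutation p = 1e-05, the smallest possible), and this held in each replicate. The difference of 258 was 425 for summits in all 3 replicates and 138 to 189, on the score of 1 replicate, leaving out 1.

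Of 13945 protein-coding genes, 4342 (31.1%) were bound, and 2905 of these (66.9%) were bound by the strongest peaks of all 3 replicates as well. Of the 22 gene lists, 8 were bound more often than other genes, 6 less often, and 8 did not pass the test. The other genes were all taken, whether active in these embryos or not. Gene activity was not measured here, and whole embryos of 0 to 24 h mix tissues and ages. A low share therefore cannot tell genes that are inactive, or active in few cells, from active genes without M1BP. Cytosolic ribosomal protein genes had 71 of 86 bound (82.6%, against 30.8% of other genes; odds ratio 10.6, Fisher's exact test, adjusted p = 7.5e-22; replicates 79.8% ± 5.50, SD, n = 3). Their strongest bound members were RpL30, RpL3 and RpLP2 with signal values of 3785, 3627 and 3214, and RpL10 and RpL10Aa were among the unbound. General transcription and RNA polymerase II genes had 38 of 46 bound (82.6%, odds ratio 10.6, exact test, adjusted p = 3.2e-12, replicates 75.4% ± 5.47). They were led by Nelf-E, a subunit of the pausing factor NELF (3110), TfIIA-L (2049) and Taf1 (1772), while Taf11 and Taf12L were unbound. The Nelf-E peak also marked a cytosolic ribosomal protein gene, so it counted for both lists.

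Of spliceosome genes 29 of 39 were bound (74.4%, exact test, adjusted p = 1.3e-07; replicates 65.0% ± 5.92), led by Sf3b6 (2801), snRNP-U1-C (2787) and Cdc5 (2078), with Prp16 and Prp19 unbound. At snRNP-U1-C replicate 2 listed no peak within 250 bp of a start site, whereas at Prp19 its best peak ranked 3657, inside its 4598 strongest. Of DNA replication genes 26 of 37 were bound (70.3%, exact test, adjusted p = 3.1e-06; replicates 64.0% ± 3.12), led by Mcm10 (1771), the helicase subunit gene Mcm5 (1442) and the clamp-loader gene RfC38 (1332), while the helicase subunit genes Mcm2 and Mcm7 were unbound. Mcm10 ranked 112 and 48 in replicates 1 and 3 but 6353 in replicate 2. Translation factors had 35 of 55 bound (63.6%, exact test, adjusted p = 3.1e-06; replicates 57.6% ± 2.78), led by eIF3d1 (2779), eIF2Bepsilon (2089) and eIF4G2 (2063), with eEF1alpha2 and eEF1delta unbound. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had 18 of 32 bound (56.3%, exact test, adjusted p = 0.00649; replicates 49.0% ± 6.51), led by GlnRS (1814), LeuRS (1480) and ArgRS-m (1258), with AlaRS and AlaRS-m unbound in the thresholded list, although AlaRS-m ranked 2508 in replicate 2.

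Respiratory chain and ATP synthase genes had 48 of 90 bound (53.3%, exact test, adjusted p = 3.6e-05; replicates 51.9% ± 2.31), led by ATPsynC, ATPsynF (2549) and the cytochrome c gene Cyt-c-p (2398), with ATPsynCF6 and ATPsynCF6L unbound. This list also holds genes named as a subunit with an added L, such as ATPsynCF6L, which were mostly unbound. Its share without them was not taken. Mitochondrial ribosomal protein genes had 42 of 75 bound (56.0%, exact test, adjusted p = 2.0e-05; replicates 53.8% ± 10.01), led by mRpS16 (2477), mRpL48 (2180) and mRpS21 (2066), with mRpL11 and mRpL12 unbound. At mRpS21 replicate 2 listed no peak, while mRpL11 ranked 3459 in replicate 3 and mRpL12 4310 in replicate 2. Among genes without an opposite start site within 1000 bp upstream, the calls of the mitochondrial ribosomal proteins (5 of 16 bound, exact test, adjusted p = 0.265) and the synthetases (3 of 10, adjusted p = 0.483) were lost. Each share stood against 17.6% of other genes (odds ratios 2.13 and 2.01), so the direction was kept on lists cut from 75 and 32 genes. Over all alternatives the call of the synthetases was lost in 8 of 15, among them peaks above the median signal value (28.1%, exact test, adjusted p = 0.318), and that of the mitochondrial ribosomal proteins in 5 of 15. Leaving out 1 replicate gave 21.9% to 28.1% for the synthetases and 24.0% to 46.7% for the mitochondrial ribosomal proteins. Both lists kept their direction in every alternative. Requiring a summit in both remaining replicates also lowered the share of bound genes on X, from 33.1% to between 17.9% and 25.5%. The calls of the 6 other lists that were bound more often held in every alternative, but their shares fell where a summit had to be in both remaining replicates after 1 was left out. These ranged from 57.0% to 72.1% for cytosolic ribosomal proteins, 45.7% to 69.6% for general transcription and 38.5% to 59.0% for the spliceosome. They ranged from 43.2% to 62.2% for DNA replication, 36.4% to 47.3% for translation factors and 28.9% to 44.4% for the respiratory chain. Each of these shares was above that of other genes in the same setting.

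**Figure D2:**
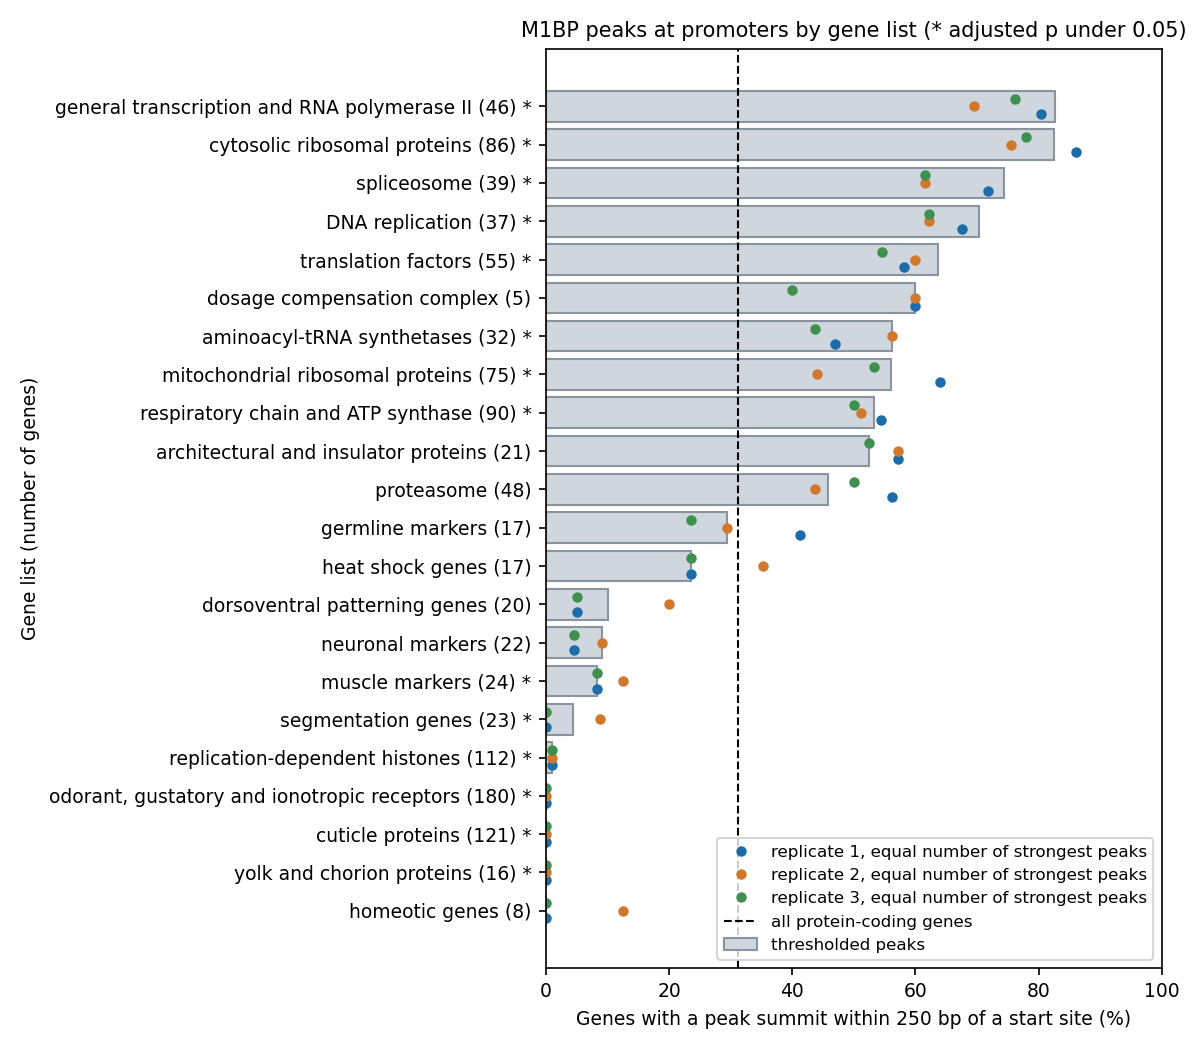
Share of genes (%) with a peak summit within 250 bp of a start site for the 22 gene lists, with list sizes in parentheses; bars are the thresholded peaks, points the 4598 strongest peaks of each replicate, the dashed line all protein-coding genes (31.1%) and asterisks adjusted p under 0.05. Shares run from 82.6% for general transcription genes to 0 for homeotic, cuticle, receptor, yolk and chorion genes.

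None of 121 cuticle protein genes (among them Ccp84Aa and Ccp84Ab; Fisher's exact test, adjusted p = 1.8e-19), of 180 odorant, gustatory and ionotropic receptor genes (among them Gr10a and Gr10b; adjusted p = 1.1e-28) or of 16 yolk and chorion protein genes (among them Cp15 and Cp16; adjusted p = 0.00801) was bound, in the thresholded list or in any replicate's strongest peaks. The histone list had 1 of 112 bound (exact test, adjusted p = 2.2e-16), and that gene was His2Av, a variant histone made outside S phase that the name pattern of the list also matched (signal value 835). The replication-dependent copies, such as His1:CG31617 and His1:CG33801, are near-identical repeats on 2L where the placement of short reads is uncertain, and so is their lack of peaks. Segmentation genes had 1 of 23 bound (4.35%, exact test, adjusted p = 0.00583), the maternal gene bcd with a signal value of 296, while the gap gene Kr and cad were unbound. Replicates 1 and 3 and the peaks left without 1 replicate bound none, bcd included, and replicate 2 bound 8.70%. Muscle genes had 2 of 24 bound (8.33%, exact test, adjusted p = 0.0221), the tropomyosin gene Tm1 (1838) and the transcription factor gene Mef2 (1830), while the actin genes Act57B and Act79B were unbound. Replicate 2 bound 12.5%. The muscle call was lost in 10 of 15 alternatives, the yolk and chorion call in 6 and the segmentation call in 3. Above the median signal value the muscle and the yolk and chorion calls failed (exact test, adjusted p = 0.282 and 0.0797). Among genes without an upstream opposite start site, the muscle, segmentation and yolk and chorion calls were lost (exact test, adjusted p = 0.0765, 0.193 and 0.236 in this order). There 0 of 21, 1 of 23 and 0 of 14 genes were bound in the same order, each against 17.6% of other genes, so the direction was kept. The muscle and segmentation calls were also lost in replicate 2 alone (exact test, adjusted p = 0.144 and 0.0538).

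The other 8 lists did not pass the test. None of the 8 homeotic genes, which set segment identity (lab, pb, Dfd, Scr, Antp, Ubx, abd-A and Abd-B), was bound in the thresholded list (exact test, adjusted p = 0.0744). This is the lowest count possible and its unadjusted p in the exact test was 0.0643. A list of 8 genes thus could not pass as bound less often in the main setting. In replicate 2 the best peak at Ubx ranked 4133, inside its 4598 strongest, and those at Scr and abd-A ranked 5098 and 5792, whereas replicate 1 ranked Ubx 18476 and abd-A 25435 and replicate 3 listed neither. Dorsoventral patterning genes had 2 of 20 bound (tok, 526, and pnr, 367; exact test, adjusted p = 0.0656), with 20% in replicate 2 and 5% in each of the others, and pnr was among the strongest of replicate 2 alone. Neuronal markers had 2 of 22 bound, the synaptic gene Syx1A (1814) and the RNA-binding protein gene elav (544; exact test, adjusted p = 0.0510), and passed in 7 of 15 alternatives. Syx1A ranked 180, 311 and 205, whereas elav ranked 16545 and 3647 in replicates 1 and 2 and had no peak in replicate 3. Heat shock genes had 4 of 17 bound (exact test, adjusted p = 0.637), which were Hsp83 (976), Hsp60A (777), DnaJ-1 (579) and Hsp27 (533). The share was 35.3% in replicate 2, which listed no peak at DnaJ-1, and 23.5% in the others. The Hsp70 copies of this list had no peak at a start site in any replicate's list. Whether short reads can be placed among these copies was not checked. Germline markers had 5 of 17 bound (vret, 1272; zpg, 1043; gcl, 1009; bgcn, 565; piwi, 386; exact test, adjusted p = 1), of which piwi ranked 9208 in replicate 2 and bgcn 4873 in replicate 3. The dosage compensation complex, which upregulates the male X, had 3 of 5 bound (msl-2, 1919; msl-3, 1286; msl-1, 382; exact test, adjusted p = 0.196), and msl-1 ranked 29458 in replicate 3. The msl-2 peak also marked a gene of the respiratory chain list. Leaving out 1 replicate gave 11.8% to 23.5% for heat shock genes and for germline markers, 4.55% for neuronal markers and 5% for dorsoventral genes. For comparison, 17.9% to 25.5% of genes on X were bound in these settings. The lists were tested against all other protein-coding genes, whose share in these settings is not given and may differ from that on X. Proteasome genes had 22 of 48 bound (45.8%, exact test, adjusted p = 0.0562) and architectural and insulator proteins 11 of 21 (52.4%, adjusted p = 0.0679). They passed in 11 and 12 of 15 alternatives, among them each replicate alone by exact tests (adjusted p = 8.1e-04, 0.0373 and 0.00667, and 0.0212, 0.0113 and 0.0372). The proteasome list also holds genes named as a subunit with an added R or T, which were mostly unbound. Its share without them was not taken.

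Motif 1, the element M1BP is named for, was the motif most enriched at its peaks. An exact match to its consensus YGGTCACACTR lay within 100 bp of 493 of 4598 summits (10.7%; 95% interval 9.86% to 11.6%) and in 0.130% of the windows 1000 bp to the left, an 82.2-fold difference (exact sign test, adjusted p = 2.6e-136; replicates 9.997% ± 0.838, SD, n = 3). With up to 1 mismatch the shares were 28.1% and 1.07%. Exact matches lay at 18.6% of peaks above the median signal value, and at 13.6% to 17.3% of peaks shared by the remaining replicates when 1 was left out. The DNA replication-related element DRE (TATCGATA), known to be bound by Dref, lay at 10.9% of peaks and 0.522% of control windows (20.8-fold, exact test, adjusted p = 1.1e-116; replicates 9.50% ± 1.47). Motif 6 lay at 4.44% against 0.196% (exact test, adjusted p = 2.0e-50) and Motif 7 at 21.1% against 7.24% (adjusted p = 4.1e-82). Smaller differences were found for the E-box (14.9% against 11.98%, exact test, adjusted p = 6.1e-05), the TATA box (3.87% against 2.37%, adjusted p = 6.1e-05) and the core of the CTCF site (1.63% against 0.565%, adjusted p = 2.2e-06). The Initiator, GAGA and the TCT initiator did not pass (exact test, adjusted p = 0.775, 0.138 and 0.306), so 7 of the 10 motifs were more frequent and none less frequent at peaks. The control windows were not matched for promoter location, whereas 84.6% of peaks lay at promoters. These differences therefore mix M1BP binding with promoter location. The comparison of bound with unbound promoters, given below, stays within promoters. Bound genes more often had an opposite start site within 1000 bp upstream, however (63.4% against 22.5% of unbound genes). That comparison was not repeated without such genes, so it may mix M1BP binding with promoter arrangement. The TATA box call was lost in 5 of 14 alternatives, among them replicate 2 alone (2.39% of its peaks). Leaving out 1 replicate gave 2.55% to 4.09% for the TATA box and 1.52% to 2.26% for GAGA. The E-box call was lost in 2, among them peaks above the median signal value (14.05%, exact test, adjusted p = 0.491). It turned in direction in 2, among them replicate 3 alone (11.6%, exact test, adjusted p = 0.974). GAGA was, by exact tests, more frequent than in control windows in replicate 2 (5.24%, adjusted p = 3.1e-08) and less frequent in replicates 1 and 3 (2.00% and 2.09%, adjusted p = 1.2e-04 and 6.1e-04).

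**Figure D3:**
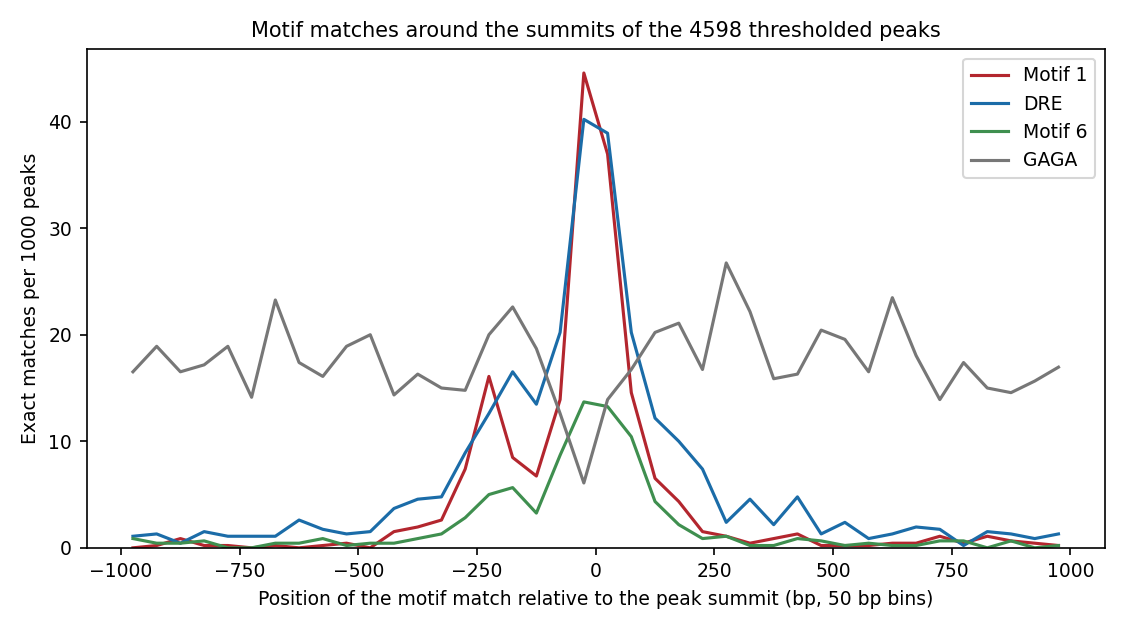
Exact motif matches per 1000 thresholded peaks in 50 bp bins from 1000 bp to the left to 1000 bp to the right of the summit on the genome; each line is 1 motif. Motif 1, DRE and Motif 6 peak at the summit, GAGA does not, and Motif 1 shows a lesser rise on the left, where 148 matches lie at 150 to 300 bp against 32 on the right.

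Bound promoters differed from unbound ones in their core elements. Within 100 bp of the most upstream start site, Motif 1 was present at 12.02% of the 4342 bound and 0.281% of the 9603 unbound promoters (odds ratio 48.5, 32.8 to 74.4; Fisher's exact test, adjusted p = 2.1e-232). Motif 6 was present at 4.35% against 0.458% (odds ratio 9.89), DRE at 14.7% against 4.74% (3.46), Motif 7 at 25.7% against 10.5% (2.95), the CTCF core at 0.990% against 0.344% (2.90) and the E-box at 18.7% against 11.5% (1.76). With 1 mismatch allowed the CTCF core did not pass (8.38%, exact test, adjusted p = 0.347). Elements known from developmentally regulated promoters went the other way: the TATA box was present at 3.27% of bound and 9.90% of unbound promoters (odds ratio 0.308, exact test, adjusted p = 2.4e-47), the Initiator at 17.6% against 34.8% (0.401, adjusted p = 1.2e-99) and GAGA at 2.05% against 4.43% (0.452, adjusted p = 7.6e-13). The TCT initiator did not differ past the threshold (16.7% against 16.5%, exact test, adjusted p = 0.768).

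Peaks with Motif 1 were stronger than peaks without. Their median signal value was 1051 (493 peaks) against 496 (4105 peaks; permutation p = 1e-05, the smallest possible), and the same direction and p were found in each replicate, with medians of 554 against 281, 323 against 135 and 213 against 111. The share of peaks with Motif 1 was 1.39%, 4.26%, 13.1% and 24.2% from the weakest to the strongest quartile of signal value, whereas the share with DRE was 10%, 11.1%, 12.01% and 10.3%. Peaks with DRE had a median of 547 against 536 (permutation p = 0.665), a test added after the data were seen. After adjacent peaks were reduced to the strongest, the Motif 1 medians were 1102 and 537. The difference of 555 between medians was 238 above the median signal value and 119 to 218 leaving out 1 replicate, where the scores are those of 1 replicate and not of the pooled list. None of the 10 strongest peaks had an exact match within 100 bp of the summit, but the match nearest to the summit at ATPsynC lay at 120 bp and that at Atg8a and BTBD9 at 136 bp. With up to 1 mismatch, 7 of these 10 had a match within 200 bp, and Lk6, Map205 and the peak between Atat and Shc had none; of these, Map205 and the Atat and Shc peak carried DRE.

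**Figure D4:**
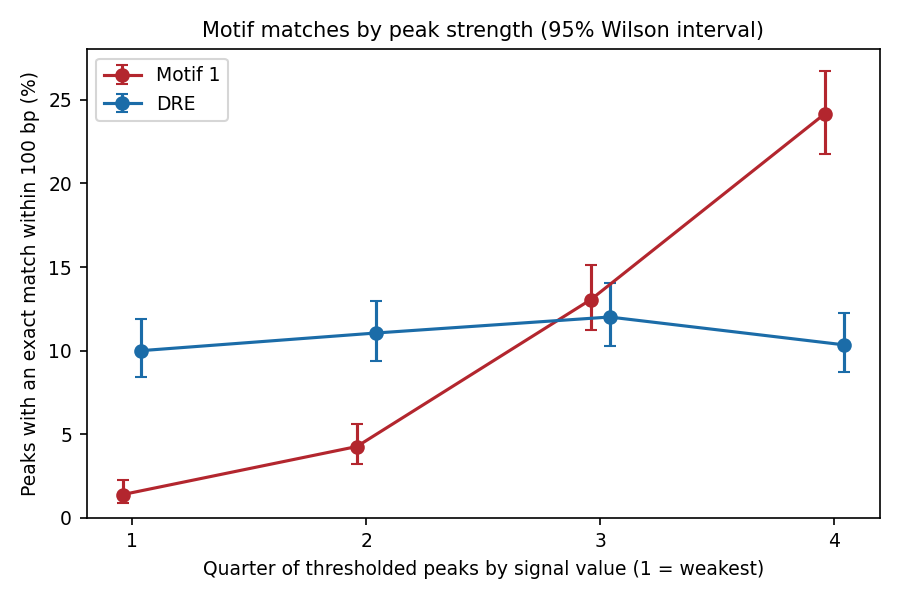
Share of thresholded peaks (%) with an exact Motif 1 or DRE match within 100 bp of the summit, by quartile of signal value; points are shares and bars 95% Wilson intervals. Motif 1 rises from 1.39% to 24.2%, and DRE stays between 10% and 12.01%.

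Divergent gene pairs were a frequent setting of M1BP peaks, as at alt and CG7655 or CG6693 and RpL3. Of bound genes 63.4% had a start site on the opposite strand within 1000 bp upstream, against 22.5% of unbound genes (odds ratio 5.96, 5.50 to 6.45; the p of Fisher's exact test lay below what the computer can represent). The replicates gave 62.6% ± 2.49 and 23.6% ± 1.71 (SD, n = 3). With the opposite start site within 250 bp, the share among bound genes was 30.6% and the direction and call were kept. Part of this follows from the definition, since 1 peak between such start sites can mark both genes.

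Chromosome 4, a small and largely heterochromatic chromosome, had 5 of 80 genes bound (6.25%) against 31.3% on the other arms (Fisher's exact test, adjusted p = 1.6e-07). The replicates disagreed, with 31.3%, 0 and 18.8% of its genes bound by the strongest peaks of replicates 1, 2 and 3 (mean 16.7% ± 15.7, SD, n = 3). On X, 33.1% of genes were bound against 30.8% on the autosomes (odds ratio 1.11, 1.01 to 1.23; exact test, adjusted p = 0.0309). That difference was lost in replicates 1 and 3 alone and turned in direction without replicate 2.

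tRNA genes, transcribed by RNA polymerase III, were rarely bound: 5 of 290 (1.72%) had a thresholded summit within 250 bp of the start, against 31.1% of protein-coding genes (Fisher's exact test, p = 1.4e-38; replicates 2.07% ± 0.345, SD, n = 3). These were tRNA:Gly-TCC-1-2, tRNA:Tyr-GTA-1-8, tRNA:Ser-TGA-2-1, tRNA:His-GTG-1-3 and tRNA:Phe-GAA-1-2, named after their values were seen, and 3 of them lay within 500 bp of a start site of a protein-coding gene. The share of bound tRNA genes was 0 at 100 bp and 6.55% at 1000 bp, and 0.690% to 1.38% leaving out 1 replicate, with the call kept.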

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

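The reduction of adjacent peaks and the restriction to genes without an upstream opposite start site were chosen after seeing the data. Of 735 comparisons with an alternative setting, 611 kept direction and side of the threshold or their value, 46 lost and 46 gained the call, 30 turned in direction and 2 moved. The promoter share stayed between 63.5% (100 bp) and 94.4% (peaks above the median signal value), and the promoter share, both signal comparisons, divergent promoters and tRNA genes kept their calls in each alternative. Counts of passing lists (10 to 18) and motifs stayed within 1.5 times of theirs. For X against autosomes, the share on X was 18.5% above the median signal value (turned), 17.7% for summits in all 3 replicates, 31.7% and 30.4% in replicates 1 and 3 alone and 23.8% at 100 bp (call lost), and 17.9% to 25.5% leaving out 1 replicate, turned without replicate 2. For chromosome 4 the call was lost in replicates 1 and 3 alone (31.3% and 18.8%), and it ranged from 0 to 13.8% leaving out 1 replicate. Replicate overlap rose to 73.2% within 250 bp and 77.8% at 1 bp of overlap. The other results that turned lay outside the threshold in the main setting, except the E-box and CTCF core. Germline markers had 23.5% bound above the median signal, 41.2% and 29.4% in replicates 1 and 2 alone, 35.3% at 500 bp, 41.2% at 1000 bp, and 11.8% to 23.5% leaving out 1 replicate. The share of other genes moves with these settings too, as that on X did above. Heat shock genes had 35.3% in replicate 2 alone and 18.2% without divergent genes, against 17.6% of other genes. The dosage compensation complex had 0 of 2 bound without divergent genes. At bound promoters, the TCT initiator had 16.5% above the median signal and in replicate 2 alone, 16.4% at 100 bp and 16.6% to 17.1% leaving out 1 replicate, and the E-box 65.3% with 1 mismatch. At peaks, the Initiator had 14.3% for summits in all 3 replicates, 15.1% in replicate 3 alone, 14.6% to 16.0% leaving out 1 replicate, and 15.9% against control windows to the right or 2000 bp to the left. GAGA had 5.24% in replicate 2 alone, 6.22% within 200 bp and 2.68% against windows 2000 bp away. The E-box had 11.6% in replicate 3 alone and, with 1 mismatch, 61.4%; the TCT initiator had 32.1% within 200 bp and 87.3% with 1 mismatch, and the CTCF core 10.03% with 1 mismatch. Short motifs with 1 mismatch match most windows by construction; the other causes were not tested. No paired analysis was possible because the series has 1 group. Without read counts, what depth limits is unknown.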

Other observations

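The tests of motif position and strand, of the 10 motifs at distant peaks and of DRE within gene lists were chosen after the main results were seen, as were those of summits within 200 bp of Motif 1, of neighbouring calls and of pairwise overlap within 500 bp.

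Motif 1 sat at the start site itself and mostly in the direction of transcription. At the 1590 bound promoters without an opposite start site within 1000 bp upstream, 249 exact Motif 1 matches lay within 200 bp of the most upstream start site, at a median position of 3 bp downstream (quartiles −24 and 20 bp). Of these, 83.1% (78.0% to 87.3%) lay on the strand of the gene (exact binomial test, adjusted p = 6.6e-27 over 3 motifs). Motif 6 had a median position of −50 bp with 76.1% of 88 matches on the strand of the gene (exact test, adjusted p = 9.2e-07), and Motif 7 a median of −8.5 bp with 71.9% of 570 (adjusted p = 4.2e-26).

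The 393 peaks over 1000 bp from any coding start site differed from promoter peaks in the frequency of 8 of 10 motifs. Motif 1 was present at 1.78% of them against 12.3% of promoter peaks (Fisher's exact test, adjusted p = 5.5e-13 over 10 motifs) and DRE at 1.02% against 12.4% (adjusted p = 6.8e-16). Motif 7 (6.11% against 23.3%, exact test, adjusted p = 1.5e-17), the E-box (6.36% against 16.4%, adjusted p = 3.1e-08) and Motif 6 (1.53% against 4.94%, adjusted p = 0.00132) were also less frequent, and the TATA box and the Initiator did not pass (adjusted p = 0.367 and 0.884). GAGA, known to be bound by Trl, was more frequent, at 5.85% against 1.93% (exact test, adjusted p = 3.3e-05), as were the TCT initiator, at 23.2% against 15.6% (adjusted p = 3.0e-04), and the CTCF core, at 3.31% against 1.36% (adjusted p = 0.00959). Promoters of annotated non-coding RNA genes accounted for few of these peaks: 6.11% (4.14% to 8.93%) lay within 250 bp of such a start. Distant peaks were also weaker than promoter peaks (median signal value 339 against 597), and motif shares were not matched for signal value. Motif 1 was present at 1.39% of the weakest quartile of all thresholded peaks, so location and strength cannot be told apart for it. DRE was present at 10% of that quartile.

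Promoter peaks without Motif 1 made up 68.2% of promoter peaks, with up to 1 mismatch allowed within 100 bp of the summit. Weak calls were argued against as the whole cause, since 39.1% (36.0% to 42.2%) of the strongest quartile had no match. They may account for part, as matches rose from 5.65% to 58.8% of all thresholded peaks from the weakest to the strongest quartile. General signal at strongly transcribed loci stays open. tRNA genes were bound less often than protein-coding genes (1.72% against 31.1%), the outcome set beforehand as against it. They are transcribed by RNA polymerase III, however, so their share does not bear on active RNA polymerase II promoters, and control libraries were not analysed. Summits set more than 100 bp from the site may account for part: of the 380 strongest-quartile peaks without a match, 27.1% (22.9% to 31.8%) had one within 200 bp, against 1.84% of windows 1000 bp to the left (exact sign test, p = 2.6e-24). Looser sites and DRE may account for others: among promoters without a closer match, one with 2 mismatches was present at 21.9% of bound and 8.99% of unbound promoters (odds ratio 2.84, 2.54 to 3.18), and DRE at 13.7% of promoter peaks without and 9.63% with Motif 1 (odds ratio 1.49, 1.19 to 1.87). How many peaks these leave was not counted, and their presence stays open.

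The rise of Motif 1 matches to the left of summits may come from second calls to the right of a stronger peak. Of the 180 exact matches 150 to 300 bp from a summit, 82.2% lay on the left; after adjacent peaks were reduced to the strongest, 49.1% (36.1% to 62.1%) of 53 did (exact binomial test, p = 1). The smallest spacing of 199 bp and the weaker right-hand member in 716 of 722 pairs fit a property of the peak caller, whose name is not given in the sources used here. No biological explanation was tested.

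Replicate 2 shared fewer of its strongest peaks with the others. A weaker enrichment that loses weak peaks alone was not decided. Of the strongest quartile of thresholded peaks, 89.2% (87.3% to 90.9%) had a summit of replicate 2 within 100 bp, under the 95% set before the test was run. The quartile is ranked on the pooled signal and displaced summits count as lost, so this share can fall without a loss of peaks strong in replicate 2. Displaced summits may account for part: within 500 bp, 82.4% of thresholded peaks were found among the strongest of replicate 2, against 85.2% in replicate 3. Pairwise overlap with replicate 2 nevertheless stayed 11.3 percentage points or more below the 86.9% of replicates 1 and 3. Dependence on GC content is a candidate explanation. Thresholded peaks with a summit of replicate 2 within 100 bp had a median GC content 4.4 percentage points (4.2 to 4.8) above those without. The difference was −0.2 in replicate 1 and −1.8 in replicate 3. It was taken at 100 bp alone, so displaced summits may enter it. The 2013 strongest peaks of replicate 2 found in neither other replicate had a median GC of 45.4%, with GAGA at 8.69% of them. Whether this arose in library preparation, in sequencing or in the embryos stays open, as the labels give no batch.

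A hypothesis that ribosomal protein promoters are bound through Motif 1 more than other bound promoters was not decided. Within 100 bp of the start site, 28.2% of the 71 bound cytosolic ribosomal protein promoters had Motif 1 at up to 1 mismatch against 30.8% of other bound promoters (odds ratio 0.881, 0.495 to 1.51; Fisher's exact test, p = 0.698). DRE was present at 28.2% of them against 14.7% of all bound promoters, and at 34.6% of the 26 bound DNA replication promoters; neither passed over 20 tests (exact test, adjusted p = 0.0666 and 0.0907).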
